A study of Homo sapiens with 15 samples.

How the data were processed

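RNA of 15 THP-1 samples was hybridised to Affymetrix human expression arrays with 54675 probe sets. The cells were untreated (0 h), exposed to infliximab for 6 or 24 h, or exposed to CDP870 for 6 or 24 h, with 3 arrays in each of the 5 groups. Groups and replicate numbers were taken from the sample labels. All 15 value columns matched a sample by name. The replicate numbers run on from 1 group to the next, so they pair no arrays.

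The values are log2 probe set summaries as deposited by the authors. The submitters' processing notes name GCRMA and GCOS 1.3.0, with no role or order, and the labels' protocols describe biotin-labelled cRNA made by the standard Affymetrix procedure. The normalization between arrays, the background settings and any filter are not given in the sources used here. The values ran from 0.17 to 11.94 with 2 decimals, and sorted values differed by at most 0.19 between arrays. The hybridisation spike-ins rose in the known order of their amounts (mean log2 of 5.54 for bioB, 6.74 for bioC, 9.21 for bioD and 10.84 for cre). The zero of the scale is unknown, so differences between groups are interpretable and a value on its own has no unit of amount. Folds are 2 to the power of the log2 difference. How the background step treated low values is not known, so the size of a fold is least certain for genes near the bottom of the scale. The similar distribution of values on all arrays means that a change shared by most genes would not be seen.

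Of the probe sets, 62 were controls and 54613 were not. Among the latter 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Of those with 1 symbol, 41037 were matched by Entrez gene number to the RefSeq annotation of GRCh38.p14, which was used for current names only. Probe sets with several symbols or none are not named as genes. A probe set was tested if its value lay above the array's own median (the 50th percentile) of the non-control probe sets on at least 3 of the 15 arrays, whatever their group. This kept 28897 probe sets of 13607 genes.

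A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so all groups share 1 estimate of the spread per probe set. The 10 comparisons were each drug and time against 0 h, infliximab against CDP870 at each time, 24 h against 6 h for each drug, the interaction of drug and time, and any difference among the groups. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was taken as a call. Errors beside log2 changes are standard errors of the model. Comparisons of single scores between groups used exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

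The comparisons, the filter, 32 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The rule names the 10 largest increases and the 10 largest decreases among calls with 1 symbol and no overlap between the values of the groups, 1 probe set per gene, for each drug against 0 h and for infliximab against CDP870. The probe set taken is the one with the largest absolute change, so the size can exceed that given for the gene in a list. It names up to 5 in each direction between times, the 5 smallest p-values for the interaction and the 5-group test, and up to 4 called members with the smallest p of each list described (2 as values where none passed). The text prints most but not all of these. Where fewer than 3 pass in a direction, 3 are given as values. TNF, TNFRSF1A, TNFRSF1B, FCGR1A, FCGR2A and FCGRT were always looked up. Of genes with several probe sets, 3 had called probe sets in both directions with infliximab at 6 h, 1 at 24 h, and 6 between the agents at 6 h (none named for these comparisons, but UBN1, 1 of the 6, is named between the times of CDP870).

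In the lists a gene is represented by its tested probe set with the highest mean. Lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests the list's genes alone. For the 32 lists fixed beforehand the adjustment covers the 31 with at least 4 tested genes. A list shift is a median over its members, and members can move either way. Overlaps of responses were set beside 100 simulations of unchanged groups that share the same controls. The fit was tested on simulated data for the comparison of infliximab at 6 h with 0 h, in 5 runs with 200 changed probe sets among 28897. It recovered 32.5% of changes of 0.5, 85.4% of changes of 1 and 97.9% of changes of 2 on the log2 scale. Of its calls 5.3% were false, and it made 0 calls in an unchanged comparison. A simulated list of 20 genes shifted by 0.5 was found in 5 of 5 runs. The simulated noise was independent between probe sets and between arrays. These rates therefore need not hold for correlated genes or for arrays that stand apart.

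Alternatives were no filter, a filter at the 75th percentile, quantile normalization again, centring each array on its median, a fit of only the arrays compared, a trended and robust variance, array weights, means of the probe sets of a gene, and each array left out in turn. Added after the data were seen were fits without 3 arrays that stood apart (control replicate 3 and infliximab 24 h replicates 5 and 6), with the mean of 18 hybridisation spike-in probe sets as a covariate, and with the 5' minus 3' difference of 16 poly-A spike-in probe sets as a covariate. The fit without the 3 arrays keeps only replicate 7 of infliximab at 24 h, so its calls for that group rest on a single array. For the results over many genes, calls were counted again over other splits of the same arrays into groups of the same sizes. No array was left out of the fit described first. No 2 arrays were copies of each other, with 2.3% to 5.6% of values identical in the 105 pairs. The arrays of each group carry consecutive running numbers, so the order of culture or processing, if it follows these numbers, cannot be separated from the groups. Scan dates and other batch labels were not used here.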

Results

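Gene expression was measured in THP-1 cells, a human line derived from an acute monocytic leukaemia and widely used as a model of monocytes. The cells were exposed to infliximab or to CDP870, and RNA was taken after 6 or 24 h. Both agents bind tumour necrosis factor (TNF). Infliximab is a chimeric IgG1 antibody, whereas CDP870 (certolizumab pegol) is a PEGylated Fab' fragment that lacks the Fc part. Untreated cells at 0 h were the only controls, so each comparison with 0 h holds the drug and the time in culture together. Each of the 5 groups held 3 arrays, 15 in all, and each array gave 54675 probe set values on a log2 scale. The median of the non-control probe sets lay between 2.93 and 3.07 on every array. The number of arrays limits the precision of every comparison. The design text of the series calls the arrays of a group biological replicates, and no other label describes separate cultures, so p-values measure the spread between these samples.

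Infliximab for 6 h was accompanied by large increases in several genes of amino acid synthesis and of the integrated stress response. ASNS, which encodes asparagine synthetase, rose 9.38-fold (log2 3.23 ± 0.11 SE, n = 3 and 3, limma adjusted p = 3.8e-10). DDIT4, a stress-induced inhibitor of mTORC1 signalling, rose 6.19-fold (log2 2.63 ± 0.1 SE, adjusted p = 1.31e-09), and VEGFA, the vascular endothelial growth factor, rose 6.08-fold (log2 2.6 ± 0.17 SE, adjusted p = 5.08e-07). The cystathionine gamma-lyase gene CTH rose 7.45-fold, the serine synthesis gene PSAT1 4.85-fold, the mitochondrial folate enzyme gene ALDH1L2 8.42-fold and the glutathione-degrading CHAC1 4.67-fold. Among the remaining genes with the largest increases were RPS6KA2, a ribosomal S6 kinase (8.21-fold), INHBE, an inhibin subunit (5.72-fold), and TM6SF1 (4.79-fold). Decreases were smaller. SPATA31C2 fell by 1.35 on the log2 scale, the translation initiation factor gene EIF5 fell by 1.02, CAD, the first enzyme of pyrimidine synthesis, fell by 1.03, and SDF2L1, a component of an endoplasmic reticulum chaperone complex, fell by 0.94 (adjusted p = 0.000263, 0.000176, 0.0131 and 0.000277). SLC2A4RG fell by 1.02, SLCO4A1 fell by 0.98, NEFH fell by 0.96, GEMIN5 fell by 0.95, POP1 fell by 0.95 and KANK1 fell by 0.94.

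**Figure D1:**
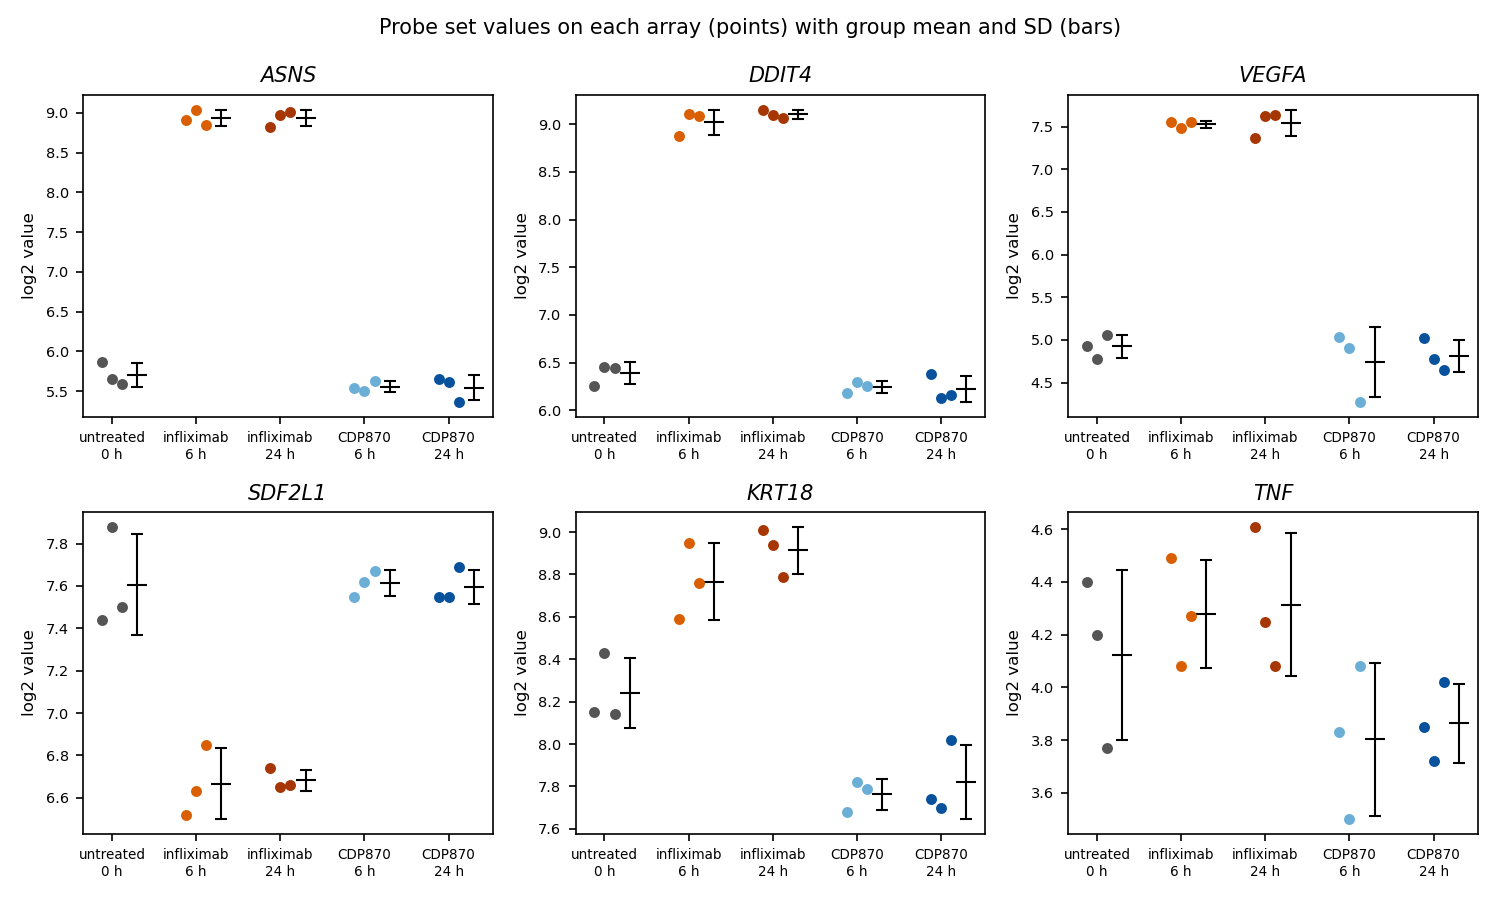
Log2 value of 6 genes on each of the 15 arrays, by group, with the group mean and SD (n = 3 per group). Group means of ASNS were 5.7 in untreated cells, 8.93 with infliximab at 6 h and at 24 h, 5.56 with CDP870 at 6 h and 5.54 with CDP870 at 24 h.

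The unfolded protein and integrated stress response list showed the strongest shift at 6 h of infliximab. Of its 19 tested genes 12 rose, 2 fell and 5 did not pass (13 rose and 2 fell adjusted over the list alone), with a median log2 change of 0.87 and a camera adjusted p of 9.46e-16. TRIB3, a pseudokinase induced by ATF4, rose by 1.38 ± 0.11 (SE), and PSAT1 by 1.86 on the probe set that represents it in the list. In the glycolysis and hypoxia list 7 of 20 genes rose and none fell (9 rose and 2 fell adjusted over the list alone). SLC2A3, a glucose transporter, rose by 1.2 ± 0.16, BNIP3L, a mitophagy receptor, by 0.92 and ANKRD37 by 1.01 on the log2 scale. The camera adjusted p of that list was 5.02e-06, and its adjusted p was 0.0944 with an estimated correlation. Of the 20 type I interferon response genes 4 rose and none fell (6 and none adjusted over the list alone), among them XAF1 by 0.72 ± 0.1 and IFIT5 by 0.82 ± 0.16 (camera adjusted p = 0.000517). Of the 11 genes of Fc gamma receptors and their signalling 3 rose and none fell (5 and none adjusted over the list alone). They were FGR, a Src family kinase (0.72), FCER1G, the receptor gamma chain (0.65), and a probe set annotated to the pseudogene FCGR1BP (0.55), with a camera adjusted p of 0.00043. Whether that probe set also measures related receptor transcripts was not tested. With an estimated correlation the stress response list kept its call (adjusted p = 0.000157), as did the interferon list and that of Fc gamma receptors and signalling (adjusted p = 0.0198 for both).

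Some genes of proliferation were lower at 6 h of infliximab. Of 22 DNA replication genes 8 fell and none rose (13 fell adjusted over the list alone), including the replicative helicase genes MCM4 (-0.64) and MCM5 (-0.47), CDC45 (-0.48) and cyclin E1, CCNE1 (-0.56). Of 22 mitosis genes 3 fell (11 adjusted over the list alone), namely CDC20 (-0.59), MKI67 (-0.6) and CENPF (-0.52). The camera adjusted p values were 0.000151 and 0.00213, and the adjusted p was 0.0544 and 0.313 with an estimated correlation. Of 11 heat shock genes 3 fell and none rose (6 fell adjusted over the list alone), with HSP90AB1 at -0.44, HSPA4L at -0.51 and HSPE1 at -0.37 (camera adjusted p = 0.000818, adjusted p = 0.0944 with an estimated correlation). In the oxidative phosphorylation list UQCRC1 (-0.35) and SDHA (-0.33) fell among 21 genes (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.0239, adjusted p = 0.342 with an estimated correlation).

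Shifts upward at 6 h of infliximab that did not hold with an estimated correlation were found in 4 lists of immune and regulatory genes. Of 14 macrophage differentiation genes 4 rose and 1 fell, with LGALS3 (0.5), PPARG (0.49) and LIPA (0.39) higher and FABP5 (-0.39) lower (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000818, adjusted p = 0.0973 with an estimated correlation). Of 18 immediate early genes 4 rose and 1 fell, among them the transcription factor genes KLF2 (0.86) and FOS (0.5) and the phosphatase genes DUSP6 (0.46) and DUSP2 (-0.44). For that list 7 rose and 1 fell adjusted over the list alone, the camera adjusted p was 0.00402, and the adjusted p was 0.158 with an estimated correlation. Of 17 cytokine and chemokine genes CCL2 (0.88) and IL18 (0.81) rose (3 adjusted over the list alone), and of 12 MHC class II presentation genes HLA-DRA (0.57) and HLA-DPA1 (0.59) rose (3 adjusted over the list alone). Both lists had a camera adjusted p of 0.0139 and an adjusted p of 0.0944 with an estimated correlation. In the epithelial marker list, fixed as a check for other cell types, 4 of 7 genes rose (6 adjusted over the list alone): EPCAM, an epithelial adhesion molecule (0.84 ± 0.1 SE), and the keratin genes KRT19 (0.62), KRT5 (0.54) and KRT18 (0.53), with a camera adjusted p of 5.02e-06 and an adjusted p of 0.0556 with an estimated correlation. Each of the other 18 lists tested had an adjusted p of 0.0532 or higher. In the list of TNF and its receptor signalling 1 of 20 genes fell and none rose, with a median of 0, a mean of -0.02 and an upward camera statistic (adjusted p = 0.699). TNF itself differed by 0.16 ± 0.19 (SE), its receptor genes TNFRSF1A by -0.14 and TNFRSF1B by 0.02, and the Fc receptor genes FCGR2A by 0.16 and FCGRT by 0.32, none past the threshold (limma adjusted p = 0.66, 0.654, 0.943, 0.414 and 0.0509). The 1 probe set annotated to FCGR1A did not reach the level needed for testing in any comparison.

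In all, limma called 2432 of 28897 probe sets between infliximab at 6 h and 0 h, 1161 higher and 1271 lower, of which 151 rose and 6 fell at least 2-fold. The larger side depended on the setting, with 1286 higher and 1276 lower after quantile normalization again. The arrays of this group also carried a higher level of the hybridisation spike-ins, RNAs added to every sample before hybridisation, at a mean log2 of 7.75 ± 0.04 (SD) against 7.38 ± 0.13 at 0 h. With that level as a covariate 181 probe sets were called and 38 of the 60 named calls were lost, among them all named cell cycle, heat shock, MHC class II, Fc gamma receptor and signalling, and keratin genes, but not EPCAM, ASNS, DDIT4, VEGFA, TRIB3, XAF1 or SLC2A3. The count was 4588 with array weights and 1614 on gene means, and leaving out 1 array gave 1487 without control replicate 3 and 1259, 1156 and 1326 without infliximab 6 h replicates 8, 9 and 10.

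**Figure D2:**
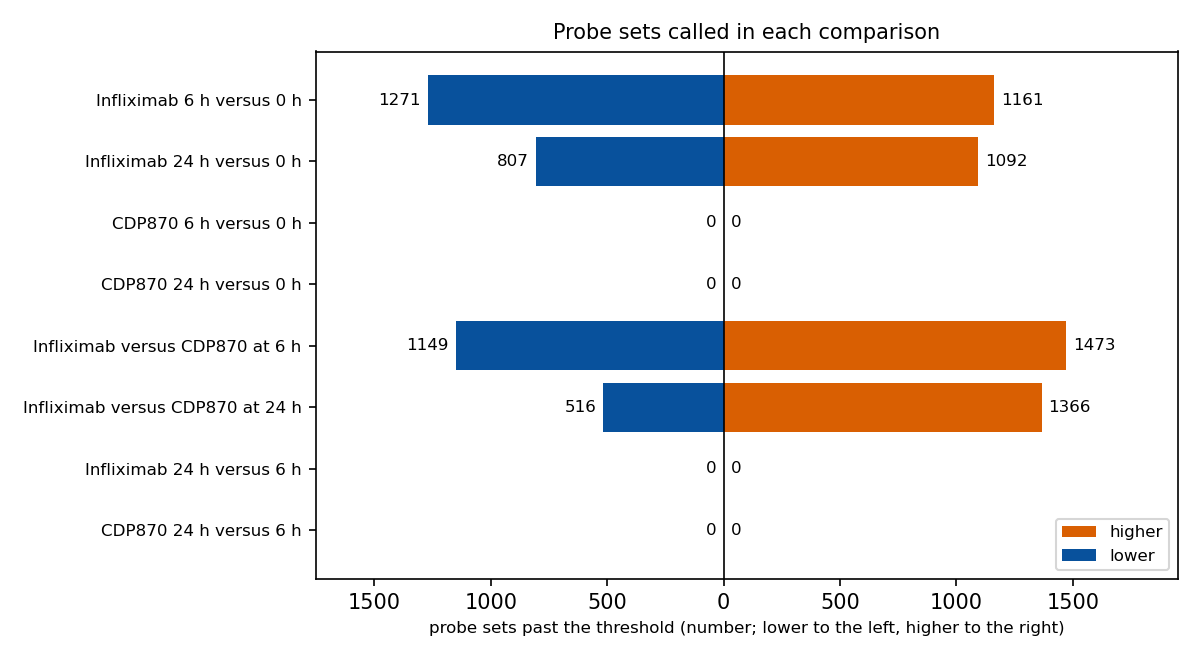
Number of probe sets past an adjusted p of 0.05 in each comparison (bars to the right: higher, bars to the left: lower, 28897 tested). Infliximab against 0 h gave 2432 at 6 h and 1899 at 24 h, and both CDP870 comparisons with 0 h gave 0.

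After 24 h of infliximab RPS6KA2 had the largest increase among the named genes and rose 14.5-fold (log2 3.86 ± 0.2 SE, n = 3 and 3, limma adjusted p = 4.27e-08), ASNS 9.38-fold (log2 3.23 ± 0.11 SE, adjusted p = 3.8e-10), ALDH1L2 8.63-fold and CTH 6.92-fold. DDIT4 rose 6.54-fold (adjusted p = 8.55e-10), ATF5, a stress-regulated transcription factor, 6.22-fold (log2 2.64 ± 0.36 SE), VEGFA 6.16-fold, INHBE 5.83-fold, CHAC1 5.49-fold and STC2, a secreted glycoprotein induced by endoplasmic reticulum stress, 5.17-fold. EIF5 fell by 1.17 on the log2 scale (adjusted p = 3.71e-05), the mitochondrial ribosomal protein gene MRPS12 fell by 0.97, ZBTB44 fell by 0.95, SDF2L1 fell by 0.92, ISOC2 fell by 0.9 and UNK fell by 0.88. ELOVL3 fell by 0.86, NEFH fell by 0.86, EBF3 fell by 0.85 and APBB2 fell by 0.84 (adjusted p = 0.0023, 0.000221, 0.00246 and 0.000118). Of the unfolded protein and integrated stress response list 12 of 19 genes rose and 2 fell (13 and 3 adjusted over the list alone), with a median log2 change of 0.88 (camera adjusted p = 1.83e-14, adjusted p = 0.00023 with an estimated correlation). SESN2, a leucine sensor of the mTORC1 pathway, rose by 1.92 ± 0.13. In the glycolysis and hypoxia list 13 of 20 genes rose and none fell (14 rose and 1 fell adjusted over the list alone), among them SLC2A3 (1.71), ANKRD37 (1.15) and NDRG1 (0.99), and this list kept its call (camera adjusted p = 2.98e-08, adjusted p = 0.0488 with an estimated correlation).

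Some immune and adhesion genes were higher at 24 h of infliximab. Of 20 interferon response genes 4 rose (5 adjusted over the list alone), with XAF1 at 1.02 ± 0.1, IRF7 at 0.72, IFI35 at 0.49 and IRF9 at 0.39 (camera adjusted p = 0.000903). Of 11 genes of Fc gamma receptors and their signalling 4 rose (7 adjusted over the list alone), namely FGR (0.76), FCER1G (0.66), FCGR1BP (0.51) and the phosphatase gene PTPN6 (0.43, and 0.28 and not past the threshold without infliximab 24 h replicate 5; camera adjusted p = 0.000318). Both lists had an adjusted p of 0.0268 with an estimated correlation. Of 19 adhesion and migration genes 4 rose and none fell (4 rose and 1 fell adjusted over the list alone): ITGAL (1.33 ± 0.21 SE) and ITGB2 (0.61), the subunits of the integrin LFA-1, CCR1 (0.51) and PECAM1 (0.48), with a camera adjusted p of 0.00932 and an adjusted p of 0.176 with an estimated correlation. Of 18 immediate early genes 7 rose and 1 fell (10 and 1 adjusted over the list alone), with KLF2 at 0.97, EGR1 at 1.01, DUSP6 at 0.51 and DUSP2 at -0.54 (camera adjusted p = 0.000685, adjusted p = 0.131 with an estimated correlation). Of 14 macrophage differentiation genes 3 rose and 1 fell (8 and 1 adjusted over the list alone), PPARG (0.57), LGALS3 (0.46) and CD9 (0.43) rising and FABP5 (-0.43) falling (camera adjusted p = 0.00261, adjusted p = 0.174 with an estimated correlation). EPCAM (0.56), KRT18 (0.67), KRT19 (0.67) and KRT5 (0.63) were among 5 of 7 epithelial markers that rose (6 adjusted over the list alone; camera adjusted p = 3e-06, adjusted p = 0.0483 with an estimated correlation).

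Some heat shock and cell cycle genes were lower at 24 h of infliximab than at 0 h. Of 11 heat shock genes 5 fell (9 adjusted over the list alone), with HSPE1 at -0.56, HSPA4L at -0.69, HSPH1 at -0.55 and DNAJA1 at -0.51 (camera adjusted p = 3e-06, adjusted p = 0.0316 with an estimated correlation). Of 22 DNA replication genes 5 fell (7 adjusted over the list alone), including MCM4 (-0.69), CCNE1 (-0.54), CDC45 (-0.35) and GINS2 (-0.36; camera adjusted p = 0.00031, adjusted p = 0.0483 with an estimated correlation). Of 22 mitosis genes CDC20 (-0.47) and CCNB1 (-0.44) fell (3 adjusted over the list alone; camera adjusted p = 0.000357, adjusted p = 0.209 with an estimated correlation). In the oxidative phosphorylation list ATP5F1C (-0.33) fell alone among 21 genes (1 fell adjusted over the list alone; camera adjusted p = 0.00195, adjusted p = 0.176 with an estimated correlation). The other 19 lists had an adjusted p of 0.0803 or higher. TNF differed by 0.19 ± 0.19 (SE), TNFRSF1A by 0.07, TNFRSF1B by 0.32, FCGR2A by 0.07 and FCGRT by 0.32, none past the threshold (limma adjusted p = 0.608, 0.859, 0.132, 0.759 and 0.057).

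Between infliximab at 24 h and 0 h limma called 1899 probe sets, 1092 higher and 807 lower (987 and 1029 after centring each array on its median), of which 151 rose and 3 fell at least 2-fold. A fit of only the 6 arrays compared called 200 (181 higher and 19 lower) and lost 35 of the 60 named calls, among them those of ITGAL, EPCAM, the keratins and every named heat shock and cell cycle gene, but not those of XAF1, KLF2, SLC2A3 or the 10 largest increases. The count was 1120 without control replicate 2. Control replicate 3 and infliximab 24 h replicates 5 and 6 stood apart from the other arrays. A fit without them, chosen after the data were seen, keeps only replicate 7 of this group, so its count is not given.

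With CDP870 no probe set passed at 6 h or at 24 h against 0 h. The 3 probe sets with the strongest evidence of a higher value at 6 h were a probe set without a single gene symbol (0.38), CA4 (0.52) and SLC6A19 (0.45; adjusted p = 0.556 for each). On the lower side they were THRAP3 (-0.64), the long non-coding RNA MALAT1 (-1.73 ± 0.28 SE) and another without a single symbol (-0.55; adjusted p = 0.173 for each). At 24 h the corresponding values were 0.52 for the mitochondrial COX1, 0.59 for ZBTB37 and 0.49 for an unnamed probe set. On the lower side they were -0.47 for DGCR11, -0.51 for OXCT2 and -0.49 for an unnamed probe set (limma adjusted p = 0.969 for each). TNF differed by -0.32 ± 0.19 (SE) at 6 h and by -0.26 ± 0.19 at 24 h, neither past the threshold (limma adjusted p = 0.997 and 0.974). TNFRSF1A differed by 0.12 and 0.13, TNFRSF1B by 0.15 and 0.02, FCGR2A by 0.01 and 0.05, and FCGRT by -0.02 and -0.03 (0.01 at 24 h after median centring).

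A few gene lists passed by camera with CDP870 although none of their members passed, and none of them held with an estimated correlation. The epithelial marker list had a median of -0.41 at 6 h (camera adjusted p = 1.7e-06, adjusted p = 0.18 with an estimated correlation) and of -0.35 at 24 h (camera adjusted p = 1.38e-06, adjusted p = 0.102 with an estimated correlation), so it lost its call at both times. Adjusted over the list alone 5 and 4 of its 7 genes fell. KRT19 lay at -0.56 and KRT18 at -0.48 at 6 h, and EPCAM at -0.37 and KRT19 at -0.46 at 24 h. At 24 h 4 further lists passed by camera and lost their call with an estimated correlation. The metallothionein list had a median of -0.2 over 7 genes, with MT1H at -0.24 and MT1G at -0.23 (camera adjusted p = 0.00117, adjusted p = 0.526 with an estimated correlation). The heat shock list had a median of 0.07, with DNAJA1 at 0.26 and HSPH1 at 0.23 (camera adjusted p = 0.00313, adjusted p = 0.257 with an estimated correlation). The unfolded protein and integrated stress response list had a median of 0.06, with XBP1 at 0.33 and HSPA5 at 0.31 (camera adjusted p = 0.00792, adjusted p = 0.102 with an estimated correlation). The mitosis list had a median of 0.05, with TOP2A at 0.18 and UBE2C at -0.2 (camera adjusted p = 0.03, adjusted p = 0.835 with an estimated correlation). Without CDP870 24 h replicate 12 the heat shock median was 0.03 and the stress response median 0, neither past the threshold, and without control replicate 3 the same held for the mitosis median of 0. The other 30 lists at 6 h had an adjusted p of 0.147 or higher, and the other 26 at 24 h of 0.114 or higher.

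The counts of 0 with CDP870 came from limma, which gave 1352 probe sets at 6 h and 1359 at 24 h with an unadjusted p under 0.05, where 1445 of 28897 would be expected by chance. For 98.9% of probe sets at 6 h and 99% at 24 h the 95% confidence interval of the difference lay within 2-fold in either direction. Array weights gave 11 calls at 6 h and 2 at 24 h, all lower, the hybridisation covariate gave 1 at 24 h, and all other settings, including each array left out, gave 0.

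**Figure D3:**
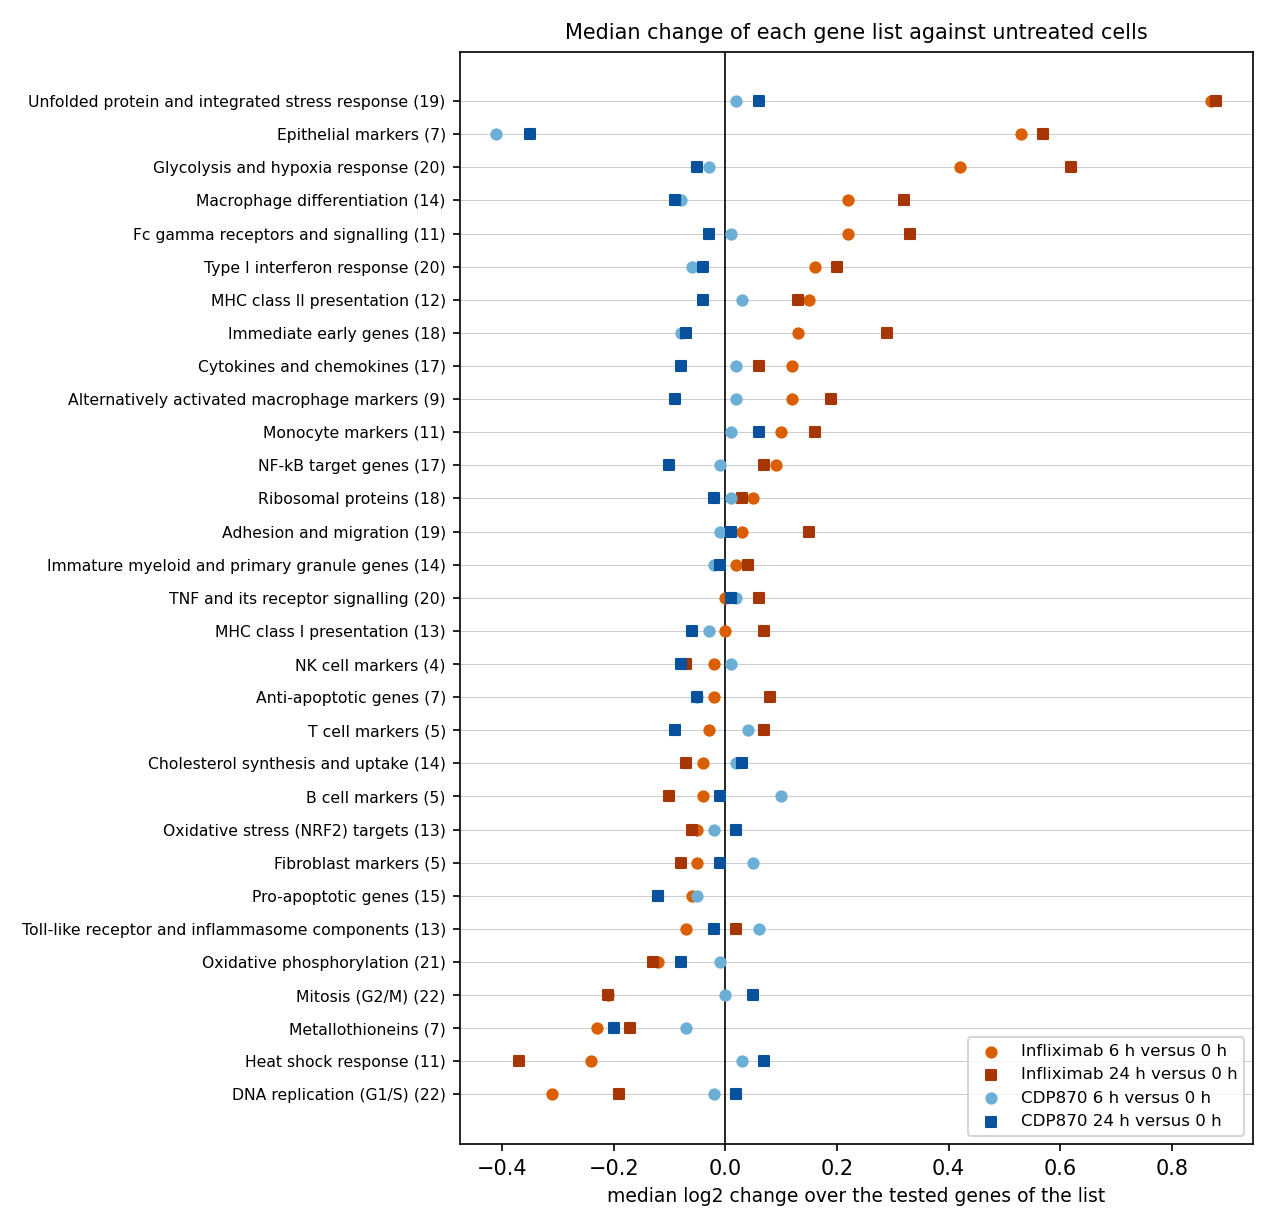
Median log2 change of each of the 31 tested gene lists in the 4 comparisons of a drug with 0 h. The unfolded protein and integrated stress response list stood at 0.87 and 0.88 with infliximab at 6 and 24 h, and the epithelial marker list at 0.53 and 0.57 with infliximab and at -0.41 and -0.35 with CDP870.

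The direct comparison of the agents at 6 h is free of the difference in time that enters the comparisons with 0 h. ASNS was 10.4-fold higher with infliximab than with CDP870 (log2 3.38 ± 0.11 SE, n = 3 and 3, limma adjusted p = 2.01e-10), CTH 8.96-fold, RPS6KA2 8.69-fold, ALDH1L2 7.89-fold and STC2 6.93-fold. VEGFA was 6.92-fold higher, DDIT4 6.84-fold (adjusted p = 6.15e-10), INHBE 6.08-fold, PSAT1 5.3-fold and TM6SF1 5.02-fold. CALR, the calcium-binding chaperone calreticulin, was lower by -1.73 ± 0.49 (SE, adjusted p = 0.0383), SLC2A4RG by -1.33, SPATA31C2 by -1.29, POP1 by -1.06, EIF5 by -1.04 and CAD by -1.03. The proteasome activator gene PSME3 was lower by -1 ± 0.25, GEMIN5 by -0.99, KANK1 by -0.98 and the transferrin receptor gene TFRC by -0.98 ± 0.11 (adjusted p = 0.000108). TNF was 0.48 ± 0.19 (SE) higher, which did not pass (adjusted p = 0.127), and neither did TNFRSF1A (-0.26), TNFRSF1B (-0.13) or FCGR2A (0.15). FCGRT, the neonatal Fc receptor, was 0.34 ± 0.09 higher (adjusted p = 0.0359), a call that ended with the hybridisation covariate (adjusted p = 0.149).

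At 6 h 4 lists differed between the agents with either correlation. In the unfolded protein and integrated stress response list 12 of 19 genes were higher and 2 lower (12 and 3 adjusted over the list alone), including TRIB3 (1.38) and PSAT1 (1.84; camera adjusted p = 6.55e-13, adjusted p = 0.000381 with an estimated correlation). Of 20 interferon response genes 6 were higher (7 adjusted over the list alone), with XAF1 at 0.83, IFIT5 at 0.94 and IFIH1 at 0.68 (camera adjusted p = 0.000278, adjusted p = 0.0205 with an estimated correlation). Of 11 genes of Fc gamma receptors and their signalling 5 were higher (5 adjusted over the list alone), among them FGR (0.67), FCER1G (0.54) and LYN (0.49; camera adjusted p = 0.000526, adjusted p = 0.0219 with an estimated correlation). EPCAM (1.21), KRT19 (1.19), KRT18 (1) and KRT5 (0.94) were among 5 of 7 epithelial markers that were higher (5 adjusted over the list alone; camera adjusted p = 1.49e-08, adjusted p = 0.0219 with an estimated correlation). The other 7 called lists lost their call with an estimated correlation, and each pair of p-values in parentheses gives the camera adjusted p and then the adjusted p with an estimated correlation. In glycolysis and hypoxia 7 of 20 genes were higher (10 higher and 3 lower adjusted over the list alone), SLC2A3 by 1.73 and BNIP3L by 1.07 (adjusted p = 3.4e-05 and 0.142). In macrophage differentiation 7 of 14 were higher and 1 lower (7 and 1 adjusted over the list alone), LGALS3 by 0.76 and CD9 by 0.66 (adjusted p = 0.000165 and 0.0773). Of the immediate early genes 6 of 18 were higher (8 adjusted over the list alone), KLF2 by 1.12 and IER2 by 0.54 (adjusted p = 0.0034 and 0.164). Of the MHC class II genes 2 of 12 were higher (4 adjusted over the list alone), HLA-DPA1 by 0.69 and HLA-DRA by 0.49 (adjusted p = 0.0484 and 0.16). In DNA replication 7 of 22 were lower (11 adjusted over the list alone), MCM10 by -0.57 and POLA1 by -0.59 (adjusted p = 0.00047 and 0.0616). In mitosis 4 of 22 were lower (8 adjusted over the list alone), CDC20 by -0.59 and MKI67 by -0.6 (adjusted p = 0.00113 and 0.255). Of the heat shock genes 5 of 11 were lower (7 adjusted over the list alone), HSPH1 by -0.57 and HSP90AB1 by -0.46 (adjusted p = 0.000165 and 0.0616). The remaining 20 lists had a camera adjusted p of 0.0547 or higher.

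At 6 h limma called 2622 probe sets between the agents, 1473 higher and 1149 lower with infliximab, 192 and 7 of them at least 2-fold. Array weights gave more on the lower side (2998 higher and 3328 lower). The count was 751 with the hybridisation covariate, which ended 20 of the 60 named calls (among them CALR, CAD, PSME3 and PPARG, but none of the 10 largest increases), 5117 in a fit of the 6 arrays alone, 6326 with array weights, 1640 on gene means and 5625 without control replicate 3 and infliximab 24 h replicates 5 and 6. Leaving out 1 array gave 1564, 1301 and 1429 without infliximab 6 h replicates 8, 9 and 10, and 1373, 1688 and 1181 without CDP870 6 h replicates 14, 15 and 16.

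At 24 h RPS6KA2 was 15.5-fold higher with infliximab than with CDP870 (log2 3.95 ± 0.2 SE, n = 3 and 3, limma adjusted p = 3.81e-08), ASNS 10.5-fold (log2 3.39 ± 0.11 SE, adjusted p = 1.87e-10), ALDH1L2 8.75-fold, INHBE 7.36-fold and DDIT4 7.34-fold. STC2 was 7.14-fold higher, CTH 7.06-fold, VEGFA 6.63-fold, ATF5 5.84-fold and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 5.23-fold (adjusted p = 9.09e-09). EIF5 was lower by -1.18 (adjusted p = 3.27e-05), the heat shock protein gene HSPH1 by -1.13 ± 0.24 (SE, adjusted p = 0.0116), the ubiquitin ligase gene SKP2 by -0.95, SDF2L1 by -0.91, UNK by -0.89 and HACD3 by -0.88. Without infliximab 24 h replicate 6 SKP2 was at -0.59 and HACD3 at -0.52, neither past the threshold. The Hsp90 co-chaperone gene FKBP4 was lower by -0.87, as were SPATA31C2 (-0.87), CHORDC1 (-0.87) and MANF, a secreted factor of the endoplasmic reticulum (-0.87 ± 0.1, adjusted p = 9.61e-05). TNF was 0.45 ± 0.19 (SE) higher, which did not pass (adjusted p = 0.186), and TNFRSF1A (-0.06), TNFRSF1B (0.31) and FCGR2A (0.02, and -0.04 after median centring) did not pass either. FCGRT was 0.35 ± 0.09 higher (adjusted p = 0.0402), a call that ended in a fit of the 6 arrays (adjusted p = 0.169).

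The lists that differed between the agents at 24 h with either correlation were 6. Of the stress response list 12 of 19 genes were higher and 3 lower (13 and 4 adjusted over the list alone), TRIB3 by 1.57 and PSAT1 by 1.75 (camera adjusted p = 6.23e-10, adjusted p = 0.00118 with an estimated correlation). Of 11 heat shock genes 7 were lower and none higher (9 lower adjusted over the list alone), among them DNAJA1 (-0.77), HSPH1 (-0.78 on the probe set that represents it in the list), HSPE1 (-0.59) and HSPA4L (-0.72; camera adjusted p = 1.43e-09, adjusted p = 0.013 with an estimated correlation). Of 20 interferon response genes 5 were higher (7 adjusted over the list alone), with XAF1 at 1.14, IRF7 at 0.78 and IRF9 at 0.59 (camera adjusted p = 0.000651, adjusted p = 0.0174 with an estimated correlation). Of 11 genes of Fc gamma receptors and their signalling 5 were higher (6 adjusted over the list alone), including FGR (0.86) and FCER1G (0.74; camera adjusted p = 0.000923), and of 22 DNA replication genes 3 were lower (6 adjusted over the list alone), MCM4 by -0.64, GINS2 by -0.32 and MCM10 by -0.42 (camera adjusted p = 8.04e-06). Both had an adjusted p of 0.0183 with an estimated correlation. The epithelial markers EPCAM (0.93), KRT19 (1.13), KRT18 (1.09) and KRT5 (0.97) were among 6 of 7 that were higher (6 adjusted over the list alone; camera adjusted p = 1.43e-09, adjusted p = 0.0174 with an estimated correlation).

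The other 9 lists called at 24 h between the agents lost their call with an estimated correlation, whose adjusted p follows the camera adjusted p in each pair of values. Of 20 glycolysis and hypoxia genes 12 were higher (14 higher and 2 lower adjusted over the list alone), SLC2A3 by 1.94 and NDRG1 by 1.11 (adjusted p = 1.44e-07 and 0.0683). Of 19 adhesion and migration genes 4 were higher (4 adjusted over the list alone), ITGAL by 1.37 and CCR1 by 0.6 (adjusted p = 0.0114 and 0.145). Macrophage differentiation had 6 of 14 higher and 1 lower (8 and 1 adjusted over the list alone), CD9 by 0.82 and PPARG by 0.66 (adjusted p = 0.000196 and 0.0808). Immediate early genes had 7 of 18 higher and 1 lower (10 and 1 adjusted over the list alone), KLF2 by 1.11 and EGR1 by 1.03 (adjusted p = 0.000651 and 0.107). Mitosis had 2 of 22 lower (6 adjusted over the list alone), CCNB1 by -0.46 and CDC20 by -0.44 (adjusted p = 3.93e-07 and 0.0916). Of 17 NF-kB target genes IER3 (0.81) and CCL2 (0.8) were higher (2 adjusted over the list alone; adjusted p = 0.0376 and 0.125). CCL2 was also the 1 gene higher among 17 cytokines and chemokines (7 adjusted over the list alone; adjusted p = 0.037 and 0.113). HLA-E (0.51) was the 1 gene higher among 13 MHC class I genes (1 adjusted over the list alone; adjusted p = 0.0303 and 0.199). No oxidative phosphorylation gene passed, with ATP5F1C at -0.21 and ATP5F1A at -0.17 (adjusted p = 0.0129 and 0.241). The other 16 lists had a camera adjusted p of 0.0956 or higher.

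At 24 h limma called 1882 probe sets between the agents, 1366 higher and 516 lower with infliximab, a split that was 1058 and 911 after centring each array on its median. A fit of the 6 arrays alone called 331 (298 higher and 33 lower) and ended 30 of the 62 named calls, among them ATF5, HSPH1, ITGAL, FKBP4 and every named DNA replication gene, and leaving out 1 array gave 2891 without infliximab 24 h replicate 7 and 1105, 1074 and 1230 without CDP870 24 h replicates 11, 12 and 13.

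Against the same 0 h arrays 709 probe sets were higher at both 6 and 24 h of infliximab, 524 were lower at both, and none was called in opposite directions. The shared controls link these lists, so no number expected by chance is given. Across probe sets, which are not independent replicates, the changes correlated at r = 0.67. In 100 simulations of unchanged groups with shared controls the mean r was 0.5, and the central 95% ran from -0.09 to 0.84. The covariance was 0.0366 above the simulated mean, whose SD was 0.00847. The infliximab and CDP870 differences share no array between 6 h and 24 h. There 790 probe sets, ASNS, DDIT4 and EPCAM among them, were higher with infliximab at both times (69.6 for independent lists, although 1 estimate of the spread serves both), 246 were lower (20.5) and 1 was called in opposite directions. These differences correlated at r = 0.53 against a simulated mean of -0.06 (central 95% from -0.63 to 0.58). Their covariance lay 0.0429 above the simulated mean (SD 0.00871). The responses to infliximab and to CDP870 against the shared 0 h arrays correlated at 0.19 at 6 h and 0.27 at 24 h (rho = 0.22 and 0.31). The simulated groups with shared controls gave means of 0.47 (central 95% from -0.05 to 0.82) and 0.46 (-0.06 to 0.83). The covariances differed from the simulated ones by -0.00569 and -0.00265, less than the simulated SDs of 0.00901 and 0.00931, and no call was shared because CDP870 had none.

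Between 24 h and 6 h of infliximab no probe set passed. The values with the strongest evidence were 0.62 for SLC19A1, the reduced folate carrier, 0.56 for BCR and 0.58 for an unnamed probe set. On the lower side they were -0.71 for SLC25A30, -0.53 for CCDC13 and -0.56 for TAPT1 (limma adjusted p = 0.3 for each). No list passed either, the lowest camera adjusted p being 0.209. The count of 0 came from limma, with 3437 probe sets at an unadjusted p under 0.05 and 1445 expected by chance, and for 96.7% of probe sets the 95% confidence interval lay within 2-fold. Without infliximab 24 h replicate 7 the count was 2462 (1831 higher and 631 lower), and every other setting gave 0.

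Between 24 h and 6 h of CDP870 no probe set passed either. The values with the strongest evidence were 0.72 for UBN1, a histone chaperone subunit with probe sets called in both directions between the agents at 6 h, 0.6 for THRAP3 and 0.6 for an unnamed probe set (adjusted p = 0.185 for each). The lower values were -0.47 for EML3, -0.59 for CEP70 and -0.36 for CDC42SE1 (adjusted p = 0.482, 0.534 and 0.536). No list passed, the lowest camera adjusted p being 0.291. Limma gave 1437 probe sets with an unadjusted p under 0.05, and for 98.8% the 95% confidence interval lay within 2-fold. Array weights gave 280 calls (123 higher and 157 lower), no filter on low values gave 1, leaving out control replicate 3 and infliximab 24 h replicates 5 and 6 gave 1, and every other setting gave 0.

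The change from 6 to 24 h was compared between the agents by an interaction term. No probe set passed, and the 5 with the smallest p included TIMM17A, a subunit of the mitochondrial import machinery (-0.67), ZBTB4 (0.86) and TGS1 (-0.71). The other two have no single gene symbol (-0.82 and 0.78). All 5 had an adjusted p of 0.365. The heat shock list (median -0.15) and the list of oxidative stress targets of NRF2 (median -0.06) passed by camera, both with an adjusted p of 0.0414, and had an adjusted p of 0.772 and 0.851 with an estimated correlation. Limma gave 2642 probe sets with an unadjusted p under 0.05. Without infliximab 24 h replicate 7 the count of the interaction was 920 (772 higher and 148 lower), and every other setting gave 0.

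A test for any difference among the 5 groups called 2726 probe sets of 1933 genes. The smallest p values belonged to ASNS (limma adjusted p = 1.74e-11), DDIT4 (4.44e-11), PCK2 (2.8e-09), PSAT1 (5e-09) and RPS6KA2 (1.11e-08). The count was 6014 with array weights, 1801 on gene means, 1695 with the hybridisation covariate, 1738 without infliximab 6 h replicate 9 and 4673 without infliximab 24 h replicate 7.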

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

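All tests in this part on spike-ins, list means, single arrays and covariates were chosen after the results were seen, as was the comparison pooled over both times, whereas the counts over splits for the 10 comparisons were planned.

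The change from 6 to 24 h differed between infliximab and CDP870 in 2 lists by camera. The heat shock list had a median interaction of -0.15 and the list of NRF2 targets, genes of the antioxidant response, a median of -0.06 (adjusted p = 0.0414 for both). Neither passed with an estimated correlation (adjusted p = 0.772 and 0.851) or with fry (adjusted p = 0.419 for both), and no single probe set passed in limma, with 2642 at an unadjusted p under 0.05. In data outside the comparisons, the hybridisation spike-ins were 0.37 higher on the infliximab 6 h arrays than at 0 h (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). The poly-A spike-ins of infliximab 24 h replicate 6 were 2.96 higher at their 3' than at their 5' probe sets.

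The mean of all 19 tested genes of the stress response list was higher on the 6 infliximab arrays than on the 6 CDP870 arrays by 0.9 (exact permutation p = 0.00216, the smallest that 6 against 6 arrays can give, higher in 6 of 6). The list was picked for its shift on these same arrays, so this p describes the separation and does not test it. The values are distributed alike on all arrays, so the spike-in level is relative to the signal of the sample. It need not measure the strength of hybridisation, and a change of the total sample signal was not tested. A higher spike-in level on the infliximab arrays as the cause is argued against at 24 h. The spike-ins there were no higher with infliximab than with CDP870 (mean log2 7.51 ± 0.15 and 7.6 ± 0.2, SD). The stress list means were 8.03 ± 0.04 and 7.12 ± 0.05. At 6 h the spike-ins were higher with infliximab (7.75 ± 0.04 and 7.5 ± 0.12), and over both times they differed by 0.08 (exact permutation p = 0.39). With the spike-in level as a covariate the median difference at 6 h of 12 stress list genes was 1.35 (mean SE 0.14) against 1.28 (0.11) without it, and all 12 stayed called. Against 0 h at 6 h it was 1.42 (0.16) against 1.32 (0.11), and 11 of the 12 stayed called. These 12 were picked as called higher between the agents at both times, so their staying called is partly fixed in advance. A culture or processing batch shared by the infliximab arrays could not be excluded, because the running numbers of the groups interleave in 0 pairs of groups, and it cannot be told apart from the drug. An effect of infliximab, or of another ingredient of its preparation, stays open as well, untested.

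The 3 arrays of infliximab at 24 h did not lie together. Replicate 7 correlated with the 6 h infliximab arrays at 0.993 to 0.995 and with replicates 5 and 6 at 0.971 to 0.982, and replicates 5 and 6 correlated with each other at 0.976. A swap of replicate 7 with a 6 h infliximab array could not be decided. Of the 6 h arrays 0 correlated better with replicates 5 and 6 (0.969 to 0.983) than with the other 6 h arrays (0.993). However, replicates 5 and 6 correlated no better with each other, so another 24 h array need not lie near them. A wrong label of replicate 7 alone stays open as well. A lower 5' yield may account for part of the distance of replicate 6, whose poly-A spike-ins had a 5' minus 3' difference of -2.96 (-1.91 to -1.34 in the other groups) and whose ACTB and GAPDH probe sets had -0.26 (-0.02 to 0.12 in the other groups), but not for replicate 5, where the spike-in difference was -1.71. No biological explanation was tested for the distance between these arrays.

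Calls were counted over other splits of the same arrays. For the 8 comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. Infliximab at 6 h against 0 h gave 2432 calls, with 0 as the highest of the other splits (1 split as large, the real one). Infliximab at 24 h gave 1899, with 841 as the highest other (1 as large). Infliximab against CDP870 gave 2622 at 6 h and 1882 at 24 h, with 0 as the highest other for each (1 as large). The comparisons of CDP870 with 0 h at 6 and 24 h and of its times gave 0, with 0 as the highest other, and infliximab at 24 h against 6 h gave 0, with 5 as the highest other, so all 10 splits were as large for these 4. For the interaction all 100 regroupings drawn gave 0 calls, as the real one did. With a real count of 0 every regrouping is as large by construction, so this count cannot speak on chance. For any difference among the groups (2726 calls, highest other 874) 1 of 100 regroupings was as large, the real one. The same held for infliximab against CDP870 pooled over both times (4613 calls, 2720 higher and 1893 lower, highest other 940), a comparison chosen after the results were seen. These shares argue against chance but rest on 100 regroupings and do not exclude it.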

How the results depend on the processing

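The alternatives with spike-in covariates and without 3 arrays that stood apart were chosen after the data were seen; the others were planned. No paired analysis was possible because the replicate numbers are unique to each array.

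None of the 242 named gene calls and 57 list calls reversed its direction under any setting, by the sign of the gene or the direction of the list test, although the median of the cytokine list at 6 h of infliximab (0.12) was -0.03 with no filter. Genes named as values without a call did change sign with 1 array left out, such as TNF at 6 h of infliximab (-0.02 to 0.3), TNFRSF1A at 24 h (-0.1 to 0.3) and FCGR2A (-0.02 to 0.13) and FCGRT (-0.07 to 0.06) at 24 h of CDP870, or moved by over 1.5 times, such as UBE2C (-0.27 to -0.09) and DNAJA1 (0.16 to 0.33) at 24 h and TNF (-0.5 to -0.17) at 6 h of CDP870. Of 242 named calls 115 held under every setting and each array left out, 83 were lost under at least 1 planned setting, 97 under an added one and 61 with an array left out. Of 57 list calls 20 held under every setting, and these were the 20 that held with an estimated correlation. Other settings called 53 to 66 lists, and leaving out an array 53 to 59. This leaves aside the setting without 3 arrays, which keeps only replicate 7 of infliximab at 24 h. The correlation of the infliximab and CDP870 responses was 0.24 at 6 h and 0.33 at 24 h with no filter, and 0.16 and 0.2 with the stricter filter.

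Array weights, which ran from 0.29 for control replicate 3 to 3.85 for CDP870 24 h replicate 11, gave 4588 calls for infliximab at 6 h, 11 and 2 for CDP870 at 6 and 24 h, 6326 between the agents at 6 h, 280 between the times of CDP870 and 6014 for any difference. Gene means, with fewer tests (13607), gave 1614 for infliximab at 6 h, 1640 between the agents at 6 h and 1801 for any difference. The fit of only the arrays compared, with fewer arrays, gave 200 for infliximab at 24 h, 5117 between the agents at 6 h and 331 at 24 h. No filter gave 1 call between the times of CDP870. The hybridisation covariate gave 181 for infliximab at 6 h, 1 for CDP870 at 24 h, 751 between the agents at 6 h and 1695 for any difference. With it the 2432 probe sets called for infliximab at 6 h had a median size of 0.47 in place of 0.52 and a median SE of 0.17 in place of 0.12; all 2432 kept their direction and 177 stayed called, so most calls ended because the error grew. Between the agents at 6 h the median size was 0.5 in place of 0.52, the median SE 0.14 in place of 0.12, and 719 of 2622 stayed called. Without the 3 arrays the counts were 984 for infliximab at 24 h, 5625 between the agents at 6 h and 1 between the times of CDP870. Apart from the growth of the error with the covariate, the cause of these differences was not tested.

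With 1 array left out the counts ran from 1156 to 1764 for infliximab at 6 h, from 1120 to 2620 at 24 h, from 0 to 0 for CDP870 at 6 h, at 24 h and between its times, from 1181 to 1688 between the agents at 6 h, from 1074 to 2891 at 24 h, from 0 to 2462 between the times of infliximab, from 0 to 920 for the interaction and from 1738 to 4673 for any difference. The arrays behind counts that moved by over 1.5 times are control replicate 2 (1120 at 24 h), control replicate 3 (1487 at 6 h), infliximab 6 h replicates 8, 9 and 10 (1259, 1156 and 1326 against 0 h; 1564, 1301 and 1429 between the agents; 1738 for any difference without replicate 9) and infliximab 24 h replicate 7 (2891, 2462, 920 and 4673). The CDP870 arrays were 6 h replicates 14, 15 and 16 (1373, 1688 and 1181) and 24 h replicates 11, 12 and 13 (1105, 1074 and 1230). The alternative for linear values was not run, as the values are on a log2 scale.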

Other observations

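The gene lists, the further epithelial genes and the tests described in this part were chosen after the results were seen, except the epithelial and other cell type marker lists.

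Many but not all genes of amino acid supply rose with infliximab in lists drawn up after the largest changes were known. The lists hold genes that prompted them, such as PSAT1 and ALDH1L2, so their p-values describe the pattern and do not test it. Of 17 cytosolic aminoacyl-tRNA synthetase genes, whose products charge tRNAs with amino acids, 11 rose and 3 fell at 6 h and 9 rose and 2 fell at 24 h (adjusted p = 0.0125 and 0.012 with an estimated correlation). WARS1 rose by 1.59, CARS1 by 1.13 and GARS1 by 1.11 at 6 h, and FARSA fell by 0.75. Of 9 serine and one-carbon enzyme genes 6 rose and 1 fell at each time (adjusted p = 0.00398 and 0.00349 with an estimated correlation), with PHGDH at 1.6, MTHFD2 at 1.48 and SHMT2 at 0.92, and MTHFD1 at -0.45 at 6 h. Of 11 amino acid transporter genes 7 rose and 1 fell at 6 h and 8 rose at 24 h (adjusted p = 0.0072 and 0.00349 with an estimated correlation), with the cystine transporter gene SLC7A11 at 1.58, SLC38A1 at 1.2 and SLC3A2 at 1.02 at 6 h.

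Some but not all chaperone genes of the endoplasmic reticulum moved the other way with infliximab, in a list also drawn up after the largest changes were known. Of 14 genes 7 fell at 6 h and 5 at 24 h and none rose (adjusted p = 0.00398 and 0.00315 with an estimated correlation), with CRELD2 at -0.86, MANF at -0.8 and PDIA4 at -0.48 at 6 h. With CDP870 no member of these lists passed in limma, and the chaperone list had a median of 0.06 at 24 h (camera adjusted p = 0.000721, adjusted p = 0.0118 with an estimated correlation). Both values are adjusted over the lists drawn up afterwards alone, so they cannot be set beside those of the planned lists with CDP870. Of 13 tested NRF2 targets 2 rose and 1 fell at 6 h and 1 rose and 3 fell at 24 h, and the list did not pass (camera adjusted p = 0.842 and 0.325). Among them SLC7A11 rose while PRDX1 fell by 0.43 at 6 h (limma adjusted p = 0.0067), and GCLM fell by 0.65 and NQO1 fell by 0.47 at 24 h (adjusted p = 0.0036 and 0.0169).

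A hypothesis was that the mitochondrial synthetase genes share the rise of the cytosolic ones. It is argued against for the 15 tested genes of the mitochondrial list. Their mean was -0.1 on the infliximab against the CDP870 arrays (exact permutation p = 0.0325, below the CDP870 mean on 5 of 6 arrays). That of the cytosolic genes, a list drawn up after the largest changes were known, was 0.4. Between the agents the mitochondrial median was -0.13 at 6 h and -0.03 at 24 h, and the list passed at neither time (camera adjusted p = 0.0664 and 0.242). Genes of the cytosolic list whose products also work in mitochondria were not set apart. Of the mitochondrial genes 1 fell against 0 h at 6 h and none passed at 24 h.

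The mean of the 7 tested epithelial markers was highest on the infliximab arrays and lowest on the CDP870 arrays, at 6.5 and 6.53 with infliximab at 6 and 24 h, 5.99 ± 0.14 (SD, n = 3) at 0 h, and 5.69 and 5.65 with CDP870. It was 0.84 higher with infliximab than with CDP870 (exact permutation p = 0.00216, higher in 6 of 6) and 0.52 higher than at 0 h (exact p = 0.0119). Exact permutation p-values of 0.00216 and 0.0119 are the smallest that 6 against 6 and 6 against 3 arrays can give. The list had already shifted on these arrays, so they describe the separation and do not test it. Whether these genes follow the change of the stress genes alone stays open. With CDP870 the mean lay at -0.32 against 0 h (exact p = 0.0119), where the stress list differed by 0.05 (exact p = 0.0952), but no member passed in limma and the list did not pass with an estimated correlation (adjusted p = 0.18 and 0.102). Epithelial cells mixed into the cultures could not be excluded. A set of 17 further epithelial genes, of which CDH1 is also in the marker list, had a median difference of 0.04 between the agents (-0.24 to 1.15). With infliximab 12 of the 17 lay above the array median. Most of these also did so with CDP870 and at 0 h, so this count is not particular to infliximab. Values are no amounts, so the level that a share of such cells would give is unknown. A batch that follows the running numbers cannot be told apart from the drugs here either, and a response of the cells to each agent was not tested separately.

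Among the markers of other cell types no list of T cell, B cell, NK cell or fibroblast genes passed in any comparison. The highest mean values in these lists were 4.29 for CD3D, 5.15 for PAX5, 5.9 for NKG7 and 5.6 for COL1A1, which cannot be read as amounts because probe sets differ in affinity. The erythroid list had 3 tested genes, too few for a test, with AHSP highest at 3.38.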
